A study of Mus musculus with 6 samples.

How the data were processed

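Total RNA of mouse lung endothelial cells was amplified, labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols, with 1 array per sample and 3 samples in each of 2 groups. The table the authors deposited holds 1 intensity per probe set and array on a linear scale. The submitters' processing notes name MAS5 and GCRMA, without versions and without saying which step each performed. From the values, the quantiles were nearly equal between arrays and a large share of probe sets lay at a floor, so the deposited values were taken as normalized between arrays and no further normalization was applied. Background correction of this kind pulls dim probe sets to nearly the same value, which makes the spread of genes at the floor very small and a fold against the floor only a lower bound.

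The table had 45101 probe sets, of which 64 were array controls. Genes were named from the platform annotation: 34958 probe sets had 1 gene, 932 had several and were not named, and 9211 were not listed and stayed unnamed here. Of those with 1 gene, 34754 were matched to a current gene of a mouse gene table through the gene number, and no symbol changed. Samples were grouped by the genotype in their labels.

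Values were taken as log2(intensity + 16), so a log2 difference understates the change of dim genes. The 40% of probe sets with the lowest mean over all 6 arrays were left out, which left 27023. For a gene with several of these, the probe set with the highest mean stood for it, giving 12279 genes. Among called genes, 932 had further probe sets, 1604 in number, of which 445 were also called in the same direction and 0 in the opposite one. The groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Values are given as mean ± SD over 3 arrays, and log2 differences, knockout minus control, with their SE. A gene below a signal of 16 in all 3 arrays of a group was taken to be at the floor there, and its fold is given against that floor as at least N-fold. Figures were drawn with matplotlib 3.10.9.

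Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over 23 lists; fry tested whether a list moved one way without comparing it with other genes. A sex-linked list was described and not tested. Of the 23 lists, 13 passed with the preset correlation, 0 with camera's estimated one (2 at an unadjusted p under 0.05) and 16 with fry. The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. That rule named Epas1, Hif1a and Arnt; the 12 genes higher and 12 lower with the largest log2 difference among those past the threshold whose groups did not overlap; up to 4 members of each list with the smallest p; and the 2 brightest members of each list of other cells. Further members of a list are named as examples after their values were seen.

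On simulated data with 12279 genes and the spread of these arrays, genes changed by 0.5, 1, 2 and 3 on the log2 scale (50 each) were recovered in 18%, 56%, 70% and 92% of cases, all with the right sign, with 8 false among 126 calls. In the same way 1 shifted list was called and 0 of the others. The simulated genes were drawn independently of each other. In the real arrays 1 common axis held 87.0% of the variance within groups. The simulation therefore cannot show how many false calls come from variation that genes share. For the same reason it cannot test the preset correlation used for the gene lists.

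The alternatives were other scalings, other filters and pseudocounts, trend and robust settings of eBayes, array weights, means of probe sets, probe sets instead of genes, the replicate number as a block, and each array left out in turn. Added after the data were seen were the spike-in level (mean of the bioB and bioC control probe sets) or the position of each array on a shared axis as a covariate, leaving out control 2 and knockout 3, averaging controls 1 and 3, and a floor on the mean signal. Chromosomes of genes were taken from a gene table of assembly GRCm38.p6, only for the order of genes.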

Results

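Gene expression was measured in mouse lung endothelial cells, the cells that line blood vessels, after 16 h at 0.5% oxygen. Per the labels, 3 arrays came from control cells and 3 from cells lacking HIF-2α, an oxygen-sensitive transcription factor encoded by Epas1. The comparison asked how expression under low oxygen differs without HIF-2α. All 6 arrays were at low oxygen, so a response to low oxygen itself cannot be read from them. The labels do not say whether the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these arrays. They also describe the controls in different ways: as carrying floxed alleles on both copies, as Cre-positive with a floxed and a wild-type allele, and as wild type. Of 12279 genes tested, 1684 differed between the groups, of which 1061 were higher and 623 lower in the knockout arrays. Controls 1 and 3 were closer to each other (SD of the log2 difference over genes 0.14) than any other pair of arrays within a group (0.31 to 0.68). Median signals of the arrays ran from 5.52 to 5.66 intensity units, and a share of 42.4% ± 0.275 of probe sets in controls and 41.8% ± 0.441 in knockouts (SD, n = 3) lay over a signal of 16. The number of arrays limits the precision.

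The Epas1 signal did not pass the test between the groups. Its bright probe set gave 9549 ± 90.9 intensity units in controls and 9392 ± 469 in knockout arrays (mean ± SD, n = 3 each), a log2 difference of -0.02 ± 0.04 (SE, limma adjusted p = 0.753). In the single arrays it read 9611, 9590 and 9444 for controls 1 to 3, and 8920, 9397 and 9859 for knockouts 1 to 3. A dimmer probe set stayed near the floor in both groups. Without knockout 1 the difference turned to 0.01. The labels do not name the deleted exons and the position of the probes was not used here, and a probe outside the deleted part checks nothing, so the genotype of the arrays rests on their labels. Among related factors, Hif1a had a log2 difference of -0.37 ± 0.17 (adjusted p = 0.22) in its brightest probe set, and -0.78 and -1.55 in its other bright ones (limma adjusted p = 0.312 and adjusted p = 0.122 over probe sets), with mean signals of 7061 in controls and 2576 in knockouts for the last. With the spike-in level of each array as a covariate, the difference of the brightest Hif1a probe set turned slightly positive. Arnt, the shared dimerization partner, had a difference of -0.36 ± 0.08 (adjusted p = 0.0534), and none of these values passed the threshold of 0.05.

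Several of the largest differences were in genes at the floor in one group, while others, such as Lama4, had clear signal in both. In the knockout arrays, Nefl, the light chain of neurofilaments, rose from the floor by at least 115-fold (log2 difference 6.48 ± 0.10, adjusted p = 0.000128). Cers6, a ceramide synthase, was at least 67.2-fold higher, and Nectin3, a cell adhesion molecule, at least 42.1-fold. Slc16a3, which encodes the lactate transporter MCT4, rose by 5.64 ± 0.18 on the log2 scale (adjusted p = 0.00113). Lama4, a laminin chain of vessel basement membranes, was higher by 3.80 ± 0.12 and Myh10, a nonmuscle myosin heavy chain, by 4.07 ± 0.15. In the other direction Peg3, an imprinted zinc finger gene, was at least 241-fold lower (log2 difference -7.56 ± 0.22, adjusted p = 0.000934). The potassium channel subunit Kcnj8 was at least 42.0-fold lower, the microsomal glutathione transferase Mgst1 at least 52.9-fold, and Asb4, which carries a SOCS box, at least 49.0-fold. Col5a1, a fibrillar collagen chain, fell by 4.11 ± 0.15 on the log2 scale and Dapk1, a death-associated kinase, by 4.26 ± 0.15.

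The other genes among the 12 largest differences in each direction were Cd276 (4.77), Ces2g (4.17), Prr36 (3.82) and Foxred2 (3.77) on the higher side, with Kbtbd11 and Zfp395, at the floor in controls, at least 29.3-fold and 25.4-fold higher. On the lower side they were Cd24a (-5.89), Stfa3 (-4.35), Nmb (-4.15), Pdzd4 (-3.97) and Tpbg (-3.96), all as log2 differences, and Btnl9, at the floor in knockouts, at least 24.8-fold lower. Slc16a3, Ces2g and Prr36 in controls, and Col5a1, Stfa3 and Pdzd4 in knockouts, had some arrays under the floor signal of 16, so their differences rest on the pseudocount and are not folds. Cd24a and Stfa3 have near-identical copies that their probes could also read, so their values are uncertain. Of these 24 genes, Nmb lost its call without control 1 or control 3 and Pdzd4 without control 1, whereas the other 22 passed with each array left out in turn. At least 2-fold differences numbered 518 among the 1684, with 322 higher and 196 lower. In 4440 genes (36.2%) the arrays of the groups did not overlap, against 10% by chance. With control 2 and knockout 3 exchanged between the groups, that number was 3861.

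The number of changed genes depended on single arrays far more than these largest differences did. The latter were picked for their size among genes called over all arrays, so most were likely to keep their calls. The number of changed genes was 205 without control 1, 203 without control 3, 316 without knockout 1, 905 without control 2, 969 without knockout 2 and 3005 without knockout 3. With controls 1 and 3 averaged into 1 sample, a choice made after the data were seen, 193 genes passed. A set of 153 genes (81 higher, 72 lower) kept its call with each array left out in turn. The share of higher genes was 63.0% over all arrays. It was 45.4% without control 1, 49.4% without knockout 1, 51.3% without knockout 2 and 53.7% without control 3, but 67.1% without control 2 and 66.1% without knockout 3. With the spike-in level of each array as a covariate it was 37.2% of 441 genes.

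**Figure D1:**
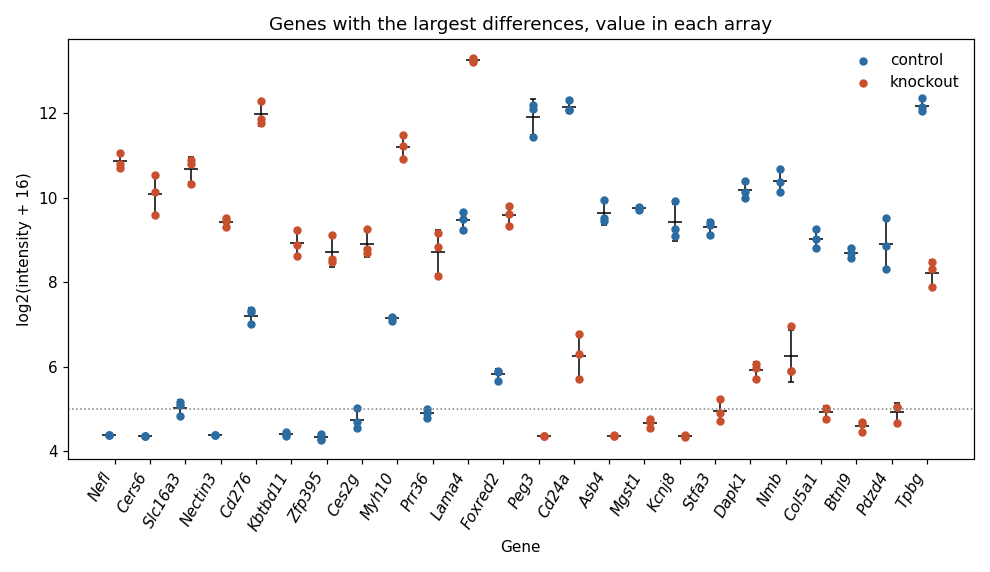
Signal of the 24 named genes with the largest differences in each of the 6 arrays, as log2(intensity + 16). Points are arrays, bars the mean ± SD (n = 3), the dotted line the floor at a signal of 16; Nefl and Peg3 lie at the floor in one group.

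Genes associated with HIF-2α were lower on balance in the knockout arrays, with exceptions such as endothelin. Among 25 measured genes associated with HIF-2α, 8 fell, 4 rose and 13 did not pass, and the counts adjusted over the list alone were also 8 and 4. Stc1, a secreted glycoprotein, fell by 1.10 ± 0.06 on the log2 scale (adjusted p = 0.00293), and Vegfa, the main endothelial growth factor, fell by 0.80 ± 0.05 (adjusted p = 0.00421). Flt1, a VEGF receptor, and the angiopoietin receptor Tek fell by 0.72 ± 0.06 and 1.24 ± 0.15. Edn1, the vasoconstrictor endothelin, and Pdgfb rose, by 2.28 ± 0.28 and 1.79 ± 0.30. The list was lower than other genes (median -0.23, camera adjusted p = 0.000634), with adjusted p = 0.354 with an estimated correlation. Of the 12 called, 4, 7 and 3 kept their calls without control 1, 2 or 3, and 4, 6 and 11 without knockout 1, 2 or 3, with Vegfa and Stc1 kept each time.

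Genes of the general hypoxia response were also lower on balance, though most did not pass. Among 28 measured, 8 fell and 20 did not pass, and 9 were lower and 1 higher when adjusted over the list alone. Mxi1, Ndrg1 and Bhlhe40 fell by 0.87 ± 0.07, 0.39 ± 0.04 and 0.56 ± 0.07 on the log2 scale, and 2, 4 and 1 of the 8 kept their calls without control 1, 2 or 3, and 2, 5 and 8 without knockout 1, 2 or 3. The list median was -0.11 (camera adjusted p = 0.000808, and adjusted p = 0.354 with an estimated correlation). With array weights it was 0.0029 and the call ended (adjusted p = 0.0519, the highest of the alternatives, which went down to 1.92e-05). Of 12 measured HIF pathway components, Ep300 and Cited2 fell, by 0.28 ± 0.04 and 0.26 ± 0.05, and 4 were lower when adjusted over the list alone. Ep300 and Cited2 both kept their calls without knockout 3, 1 of them without control 2, and 0 without any other single array. Its test gave adjusted p = 0.0199, and adjusted p = 0.274 with an estimated correlation. The call ended in several alternatives, among them without knockout 3 (0.0502), with a range of 0.00236 to 0.121. Glycolysis and glucose uptake did not pass as a list with camera (median 0.04, adjusted p = 0.325, and adjusted p = 0.811 with an estimated correlation). With fry, which does not compare a list with other genes, the list was called higher (fry adjusted p = 0.0244). Of its 19 measured members Slc16a3 and Pfkp (log2 difference 0.18 ± 0.03) rose, 17 did not pass, and the counts adjusted over the list alone were the same. Slc16a3 kept its call with each array left out, whereas Pfkp lost its call in every case but without knockout 3, leaving 1 called gene.

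Vessel growth and endothelial genes were lower on balance. The lists share called genes, so their tests are not independent of each other. Of the called angiogenic genes, Vegfa, Flt1, Tek, Edn1 and Pdgfb are also on the HIF-2α list, and Vegfa on the general hypoxia list. Flt1, Tek and Tie1 are also on the endothelial identity list, Flt4 on the lymphatic list and Efnb2 on the Notch list. Of 30 angiogenic ligands and receptors, 9 fell and 4 rose, with 10 and 4 adjusted over the list alone. Vegfc, the lymphatic growth factor, fell by 1.22 ± 0.07 on the log2 scale and its receptor Flt4 by 1.23 ± 0.11, while Edn1 and Pdgfb were among those that rose. The list median was -0.09 (adjusted p = 0.0056, and adjusted p = 0.492 with an estimated correlation), and ran from -0.23 to -0.0097 over the alternatives. Its call ended with array weights (0.0618) and without control 2 and knockout 3 (0.0894), in a range of 0.000391 to 0.0894. Of its 13 called genes, 4, 8 and 2 kept their calls without control 1, 2 or 3, and 5, 9 and 12 without knockout 1, 2 or 3. Of 14 genes of Notch signalling and arterial identity, 5 fell and 9 did not pass (6 lower adjusted over the list alone), among them the Notch ligand Dll1 (-0.92 ± 0.11) and the guidance receptor Unc5b (-1.17 ± 0.18). That list had a median of -0.33 (adjusted p = 0.00362, and adjusted p = 0.274 with an estimated correlation). Over the alternatives its median ran from -0.56 to 0.00054, the last without a filter, where genes at the floor are members. Of the 5 called genes, 1, 1 and 0 kept their calls without control 1, 2 or 3, and 0, 3 and 5 without knockout 1, 2 or 3.

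Endothelial identity genes included 7 that fell and 1 that rose among 35, with 7 and 4 adjusted over the list alone. Nos3, the endothelial nitric oxide synthase, fell by 0.53 ± 0.05 and the transcription factor Ets1 by 0.50 ± 0.05. The median was -0.08 (adjusted p = 0.000634, and adjusted p = 0.354 with an estimated correlation). Of 8 measured lymphatic endothelial genes, Stab2, Flt4 and Itga9 fell (4 lower adjusted over the list alone), with log2 differences of -2.30 ± 0.07, -1.23 ± 0.11 and -2.09 ± 0.29. Lyve1 was bright in both groups (19571 ± 981 and 17478 ± 396, adjusted p = 0.0819) and Prox1, the regulator of lymphatic fate, was at the floor. This list had a median of -0.10 (adjusted p = 0.0051, and adjusted p = 0.354 with an estimated correlation), which ran from -1.23 to -0.02 over the alternatives. Of the 8 called endothelial identity genes, 1, 5 and 0 kept their calls without control 1, 2 or 3, and 1, 6 and 6 without knockout 1, 2 or 3. Of the 3 lymphatic genes, 1, 2 and 1 did without control 1, 2 or 3, and 2, 3 and 3 without knockout 1, 2 or 3, with Stab2 kept each time.

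**Figure D2:**
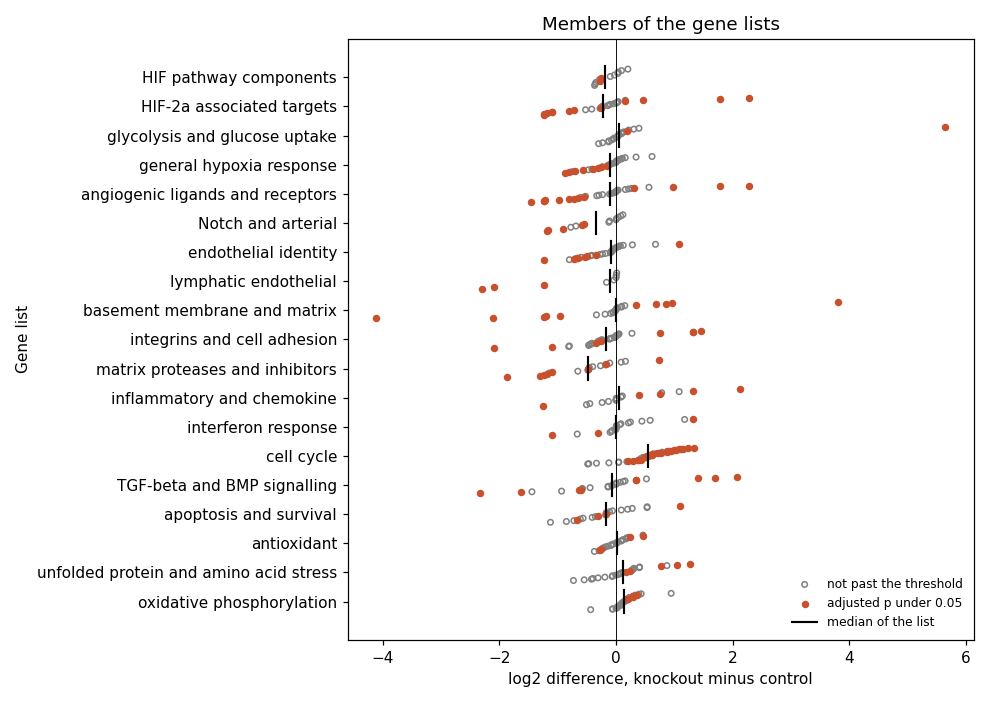
Log2 difference (knockout minus control) of each measured member of 19 gene lists. Filled points passed the threshold of 0.05, open points did not, and black bars are list medians; the cell cycle list lies to the right with a median of 0.54 and matrix proteases to the left with -0.47.

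Matrix proteases were lower on balance in the knockout arrays, and their inhibitors went both ways. Of 19 measured proteases and inhibitors, 8 fell and 1 rose, or 11 and 1 adjusted over the list alone. The metalloproteases Adamts1 and Adamts9 fell by 1.23 ± 0.06 and 1.30 ± 0.10 on the log2 scale and passed with each array left out, and the tissue plasminogen activator Plat fell by 1.19 ± 0.13. Of the 9 called, 2, 5 and 2 kept their calls without control 1, 2 or 3, and 2, 7 and 9 without knockout 1, 2 or 3. Timp1, an inhibitor of metalloproteases, rose by 0.74 ± 0.14, and Timp2, another, fell by 0.47 ± 0.08. The median was -0.47 (adjusted p = 2.26e-06, and adjusted p = 0.233 with an estimated correlation). Matrix genes went both ways, with 5 of 24 higher and 5 lower (the same adjusted over the list alone), a median of -0.0064, which turned positive under the quantile and 75th percentile scalings, and adjusted p = 0.336 (0.811 with an estimated correlation). Of its 10 called genes, 5, 7 and 5 kept their calls without control 1, 2 or 3, and 3, 8 and 10 without knockout 1, 2 or 3. Beside Lama4 and Col5a1, the basement membrane protein Nid2 was at least 4.28-fold lower. Of 32 integrins and adhesion genes, 4 rose and 4 fell (the same adjusted over the list alone), including Vcam1 (1.32 ± 0.18) and Selp (-1.10 ± 0.09), receptors for leukocytes. Its median was -0.17 (adjusted p = 0.0215, and adjusted p = 0.274 with an estimated correlation), and the call ended without knockout 1 (0.0522) or knockout 3 (0.0502), in a range of 0.00273 to 0.136 over the alternatives. Of its 8 called genes, 1, 1 and 0 kept their calls without control 1, 2 or 3, and 2, 3 and 7 without knockout 1, 2 or 3.

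Cell cycle genes were higher as a group. Of 41 measured, 26 rose and 15 did not pass (30 higher adjusted over the list alone), with a median log2 difference of 0.54. Pole, a subunit of DNA polymerase epsilon, rose by 0.92 ± 0.05 (adjusted p = 0.00333), the mitotic cyclin Ccnb2 by 1.12 ± 0.12, the replication helicase subunit Mcm5 by 0.78 ± 0.09 and the mitotic regulator Birc5 by 0.54 ± 0.07. The list test gave adjusted p = 1.29e-08, and adjusted p = 0.274 with an estimated correlation. The list kept its call in all 23 other settings tested with the preset correlation, but of the 26 genes 1 kept its call without control 1, 3 without control 3, 1 without knockout 1, 10 without knockout 2 and 17 without control 2. Of 37 genes of oxidative phosphorylation, 6 rose and 31 did not pass (10 higher adjusted over the list alone), including Cox7a2 (0.20 ± 0.02) and Ndufv2 (0.29 ± 0.04). Of the 6, Cox7a2, Cox5a (0.29 ± 0.04) and Sdhd (0.36 ± 0.05) lie on chromosome 9, whose genes were higher as a set by a median of 0.29. That list had a median of 0.14 (adjusted p = 0.000634, and adjusted p = 0.605 with an estimated correlation), and its call ended with the spike-in level as a covariate (adjusted p = 0.165, in a range of 0.000266 to 0.165). Of the 6 called genes, 0, 4 and 0 kept their calls without control 1, 2 or 3, and 0, 3 and 6 without knockout 1, 2 or 3.

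Inflammatory and signalling lists held changed genes in both directions and did not pass as lists. Of 16 inflammatory genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), among them the cytokine Csf1 (2.13 ± 0.22), Vcam1 and Icam1 (0.75 ± 0.13), with a median of 0.05 and adjusted p = 0.46 (0.811 with an estimated correlation). Of 20 interferon response genes, Irf1 rose by 1.32 ± 0.25 while Ddx58 and Isg20 fell (the same adjusted over the list alone), and the list's median (0.0046) and mean (0.09) were above 0 while its test pointed down (adjusted p = 0.785, or 0.92 with an estimated correlation). Of 25 TGF-β and BMP genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone), with adjusted p = 0.524 (0.811 with an estimated correlation). The latent TGF-β binding protein Ltbp1 and the ligand Tgfb2 rose by 1.69 ± 0.09 and 1.41 ± 0.11, and the matrix protein Tgfbi fell by 2.33 ± 0.21. Of these lists' called genes, Ltbp1 and Tgfb2 were those that passed with each array left out; of the 5 inflammatory, 3 interferon and 9 TGF-β genes, 0, 0 and 2 kept their calls without control 1, 1, 1 and 6 without control 2, and 0, 0 and 3 without control 3. Without knockout 1 these numbers were 1, 1 and 4, without knockout 2 they were 1, 1 and 6, and without knockout 3 all kept their calls.

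Among stress and survival genes, the amino acid transporter Slc7a5 and Birc3, an inhibitor of apoptosis, rose the most. Of 21 apoptosis genes, 3 fell and Birc3 rose, by 1.10 ± 0.16 (the same adjusted over the list alone), with Mcl1, a survival factor, at -0.18 ± 0.03. The list median was -0.18 (adjusted p = 0.0367, and adjusted p = 0.274 with an estimated correlation), and the call ended without control 1 (0.0638), knockout 1 (0.0522) or knockout 2 (0.0583), in a range of 0.00241 to 0.323 over the alternatives. Of 23 antioxidant genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone), including Gpx1 (0.25 ± 0.04), with a median of 0.0146, a mean of -0.0011 and a test that pointed down, and adjusted p = 0.476 (0.811 with an estimated correlation). Of 25 genes of the unfolded protein and amino acid response, 5 rose and 20 did not pass (the same adjusted over the list alone), including Slc7a5 (1.27 ± 0.15) and Chac1 (1.05 ± 0.20), and the test gave adjusted p = 0.214 (0.811 with an estimated correlation). It passed without control 2 and knockout 3 (0.034, in a range of 0.034 to 0.927). Of the 4 apoptosis, 4 antioxidant and 5 unfolded protein genes called, each list kept 0 without control 1, control 3 or knockout 1 and 1 without control 2, and they kept 1, 0 and 1 without knockout 2 and 3, 2 and 5 without knockout 3.

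Markers of other lung cells were mostly at the floor in all 6 arrays. Fibroblast collagen genes Col1a1 and Col3a1 read 5.06 and 5.15 in controls, and none of 6 measured fibroblast genes passed (limma, 0 at an unadjusted p under 0.05; list adjusted p = 0.639, or 0.811 with an estimated correlation, with a median of 0.0031, a mean of -0.0066 and a test that pointed down). Smooth muscle Acta2 was at 4.77 in controls and 4.80 in knockouts, and of 6 measured genes only Smtn, a smooth muscle protein, rose, from 693 ± 108 to 1774 ± 271, while Mylk (10058 ± 222 and 9704 ± 141, adjusted p = 0.23) and Tagln (50.3 ± 22.1 and 148 ± 70.5, adjusted p = 0.144) did not pass (list adjusted p = 0.638, or 0.811 with an estimated correlation). Among leukocyte genes Ptprc, the common leukocyte antigen, read 4.31 and 4.32, while Cd68 fell from 3925 ± 293 to 971 ± 192, Cd53 from 1286 ± 159 to 384 ± 129 and Cd14 from 183 ± 49.5 to 30.4 ± 10.6. Coro1a went the other way, with a log2 difference of 1.18 ± 0.38, and did not pass (limma adjusted p = 0.111). With 3 of 7 lower and 4 not past the threshold, the leukocyte list had adjusted p = 0.0473, and adjusted p = 0.278 with an estimated correlation; the call ended without control 1 (0.0635) or any 1 of knockouts 1 to 3 (0.0648, 0.0749 and 0.0928), in a range of 0.0138 to 0.192 over the alternatives. Of the 3 leukocyte genes 0, 2 and 0 kept their calls without control 1, 2 or 3, and 1, 3 and 3 without knockout 1, 2 or 3; Smtn and Ager lost theirs without control 1, control 3 or knockout 1, and Ager also without knockout 2 or 3. Of 6 lung epithelial genes Ager fell by 0.89 ± 0.16 on the log2 scale, Hopx (1581 ± 310 and 793 ± 176, adjusted p = 0.0538) did not pass, Sftpc was at 6.09 and 6.26, and the list, with a median of 0.0017 but a mean of -0.31, gave adjusted p = 0.244 (0.768 with an estimated correlation). Counts adjusted over each of these lists alone were the same, except 2 lower for the epithelial list. With fry the smooth muscle list was called higher (fry adjusted p = 0.031) and the epithelial list lower (fry adjusted p = 0.0412).

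RNA quality was read from control probe sets at the ends of abundant transcripts. The log2 difference between the 3' and 5' control probe sets was 0.36 ± 0.02 in controls and 0.34 ± 0.02 in knockouts for Gapdh (n = 3 each, two-sided exact permutation p = 0.4) and 0.61 ± 0.07 and 0.53 ± 0.04 for beta-actin (exact permutation p = 0.2). The level of the spike-in controls was 10.76 ± 0.11 and 10.98 ± 0.12 on the log2 scale (exact permutation p = 0.2). With 3 arrays against 3, the smallest p such a test can give is 0.1. Genes of chromosome 9 were higher as a set in the knockout arrays (median 0.29 above all genes with a mean above 9 on the log2 scale); of the genes named, Birc3, Ccnb2, Cd276, Cox5a, Cox7a2, Gpx1, Icam1 and Sdhd, which rose, and Ets1, Itga9 and Tpbg, which fell, lie there. All 12 probe sets of sex-linked genes stayed at or under a signal of 6.37 in every array.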

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

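Tests of the shared axis, of the swap and of chromosome 9 were chosen only after the results they measure had been seen. Outside the measurement of named genes, 179 of 4463 probe sets that name no single gene changed between the groups (4.01%, against 8.36% of the named ones), with 89 higher and 90 lower in the knockout arrays. They were looked at because they lie outside the genes tested.

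Of the 10 splits of the 6 arrays into 3 and 3, the real split gave 1684 genes and was the 1 split that gave as many, and the highest of the others gave 12. The design has too few splits for a share under 0.05. The split with 12 is the one that exchanges control 2 and knockout 3, and before adjustment it came close to the real one: 3394 genes against 3981 at a p under 0.05, 3861 against 4440 with groups that did not overlap, and 89 against 112 of these at least 4-fold apart.

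The arrays of both groups varied along 1 common axis, which held 87.0% of the variance within groups, with control 2 apart from controls 1 and 3 and knockout 3 apart from knockouts 1 and 2; it runs partly along the group comparison, with an r of -0.53 across genes between gene score and group difference (genes are not independent replicates) and positions of 29.2, -8.32 and 32.5 in controls and -25.9, -50.9 and 23.3 in knockouts. Hybridization of the arrays is a candidate explanation, since the spike-in level followed the axis after the group means were removed (Pearson r = -0.90, permutation p = 0.0556, 6 arrays, 36 permutations). Spearman rho was -0.89 (permutation p = 0.0833), and r was -0.82 without the 2 arrays farthest out. The permutation p adjusted over 4 relations was 0.111 for r and 0.167 for rho. Labelling of the sample RNA was not measured by the spike-in level. RNA quality stays open, because the 3' to 5' difference followed the axis for beta-actin (r = 0.83 and rho = 0.89, each with permutation p = 0.0278, the smallest these can give, and adjusted p = 0.111; r = 0.98 without the 2 farthest) but less for Gapdh (r = 0.435, permutation p = 0.444, adjusted p = 0.444; rho = 0.54, permutation p = 0.306, adjusted p = 0.306; r = 0.63 without the 2 farthest), and the 18S signal gave r = -0.79 and rho = -0.77 (each with permutation p = 0.167 and adjusted p = 0.222; r = -0.92 without the 2 farthest). A swap of control 2 and knockout 3 was looked at in 405 genes at least 4-fold apart between the other 4 arrays. Of these, 32.6% had both arrays nearer to their own group and 32.1% both nearer to the other. Control 2 was nearer to its own in 66.7% and knockout 3 in 33.8%. These genes were picked from arrays at opposite ends of the axis, so the axis and a swap cannot be told apart by them. A further test, chosen after that one, took 57 genes on in 1 group and off in the other among the other 4 arrays. Of these, 34 had both arrays with their own group and 14 both with the other. Over all genes, 25 were on and off by the labelled split and 2 by the exchanged one (43 and 10 at a lower limit, 11 and 0 at higher ones), which leans to the labels. Genes of chromosome 9 argue against a swap. Their median excess over all genes was 0.28 to 0.32 in all 9 pairs of a knockout and a control array. A swap would put control 2 with knockouts 1 and 2, and knockout 3 with controls 1 and 3, with little excess in those pairs. No biological explanation of the axis was tested.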

How the results depend on the processing

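Settings with spike-in level, shared axis, controls 1 and 3 as 1 sample, control 2 and knockout 3 left out, or a floor on the mean signal (1929 genes) were chosen after the data were seen. The count of 1684 genes stayed within 1.5 times under the other scalings, pseudocounts, the stricter filter, trend and robust settings and means of probe sets (1424 to 1880). Probe sets instead of genes gave 2066 of 27023, a count of another unit that includes 179 without a single gene. Of the named probe sets 8.36% changed, against 13.7% of the genes. The count of genes moved to 885 (514 higher, 371 lower) without a filter, where more genes are tested, to 2922 at an adjusted p under 0.10 and to 518 at 2-fold or more. Array weights gave 8533 (5008 higher, 3525 lower) and a log2 difference of -0.10 for Epas1, past the threshold, but their estimate stopped before it converged. With each array left out the count ranged from 203 to 3005, the higher genes from 93 to 1985 and the lower from 94 to 1020. The spike-in covariate gave 441 (164 higher, 277 lower, 360 of them shared), the axis covariate 3660 (1986 and 1674, 1592 shared), leaving out control 2 and knockout 3 4628 (2944 and 1684), and controls 1 and 3 as 1 sample 193 (95 and 98). Leaving out arrays or adding a covariate leaves fewer degrees of freedom, yet the count rose in some of these settings. Among them were the fits without knockout 3 and with the axis covariate. The axis was computed from the deviations of these same arrays within groups and held 87.0% of that variance. As a covariate it lowers the spread within groups by construction, so that rise is no support for the calls. Control 2 and knockout 3 lay apart from their groups, so leaving both out also narrows the groups. Other causes of the shifts in count were not tested. The Epas1 log2 difference turned to 0.13 with the mean of its probe sets, 0.0275 with the spike-in level and 0.00404 with the axis, and ranged from -0.0605 to 0.0115 with arrays left out; Hif1a turned to 0.0045 with the spike-in level. With an estimated correlation 0 lists passed, and with preset correlation 10 to 13 did with arrays left out; 6 of the 13 lists kept their call in all 23 other settings.

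Whether the replicate numbers pair the arrays was not settled. Deviations of same-numbered arrays correlated over genes at -0.46, 0.84 and 0.80. Arrays 2 and 3 of each group correlated best with their own number, and control 1 and knockout 1 did not. With 1 axis holding 87.0% of the variance within groups, these correlations cannot tell pairing from positions on that axis. With a replicate block, 2993 genes passed (2076 higher, 917 lower), and the HIF component and leukocyte lists lost their calls (adjusted p = 0.0534 and 0.0692). Signal over background limits the genes at the floor, whose folds are bounds.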

Other observations

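The genes and tests in this part were chosen after their values were seen. Among genes of secreted factors, Igf1, a growth factor, was at the floor in controls and at least 10.4-fold higher in the knockout arrays, and Csf1 rose by 2.13 ± 0.22 on the log2 scale. The neuropeptide genes Calcb, Nts and Nmb fell by 3.43 ± 0.31, 2.57 ± 0.36 and 4.15 ± 0.36, and Gas6, a ligand of the TAM receptors, fell by 3.21 ± 0.26. Scd1, a fatty acid desaturase, rose by 3.19 ± 0.29. The hypoxia-induced genes Adm and Angptl4 had log2 differences of 0.02 ± 0.02 and 0.04 ± 0.08, neither past the threshold (adjusted p = 0.706 and 0.829). Igf1 kept its call with each array left out, Scd1 lost it without control 1 and Gas6 without control 3. Calcb and Nmb lost theirs without control 1 or 3, Csf1 without control 1, control 3 or knockout 1, and Nts without control 3, knockout 1 or knockout 2.

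Imprinted genes went both ways, and were not tested as a list. Beside Peg3 and Asb4, Peg10 fell by 0.74 ± 0.11 and Mest by 0.19 ± 0.02, Igf2 rose (at least 2.43-fold), and Grb10, Sgce, Impact and Gnas did not pass (adjusted p from 0.121 to 0.991). Peg3 and Asb4 kept their calls with each array left out, whereas Mest, Igf2 and Peg10 lost theirs without control 1, control 3 or knockout 1, and Peg10 also without control 2.

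Medians of the chromosomes were compared over 7378 genes with a mean above 9 on the log2 scale. The median difference of the 393 genes of chromosome 9 was 0.29 above that of all genes (95% bootstrap interval 0.25 to 0.36), against at most 0.12 for any other chromosome. Intervals here and for the lower chromosomes come from resampling genes with the arrays held fixed, so they do not measure the spread between arrays. The excess of chromosome 9 was positive in all 9 pairs of a knockout and a control array, which share the 6 arrays. Chromosome 2, at 0.03, was also above 0 in all 9 pairs. The axis shared by the arrays of both groups as the whole cause is argued against for chromosome 9 by an excess of 0.30 with the axis as a covariate. A share of 77.1% of the chromosome 9 genes was higher, against at most 66.4% elsewhere. A few strongly changed genes could hardly move a median of 393 genes, so this share is no separate test of them. Extra copies of the whole chromosome stay open: 1 of 6 stretches had an excess of 0.06 and the others 0.29 to 0.39, a lowest value reached in a share of 0.0012 of 10000 shuffles of gene positions, but 11 of 19 other chromosomes also gave a share under 0.05 in the same kind of shuffle, and the test was chosen after the low stretch had been seen, in place of a criterion those values could hardly have met. A gain of part of the chromosome, a difference in strain background or the knockout itself may be considered but was not tested, and at other limits on mean signal the excess was 0.20 to 0.30.

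On the lower side, chromosomes 19 and 16 had differences of -0.17 (-0.22 to -0.11) and -0.16 (-0.27 to -0.11) against all genes, below 0 in all 9 pairs, and -0.19 and -0.17 with the axis as a covariate. Chromosomes X and 18 had -0.14 (-0.23 to -0.06) and -0.13 (-0.21 to -0.05), in intervals that overlap these, but -0.0014 and 0.01 with that covariate. Chromosome 5, at -0.01, was also below 0 in all 9 pairs.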
